A study of Homo sapiens with 24 samples.

How the data were processed

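The series holds 24 Affymetrix arrays of total RNA labelled with biotin by the one-cycle procedure, per the labels. MCF-7, ZR75-1, MDA-361 and HCC-1428 are established human breast cancer cell lines. LTED stands for long-term estrogen-deprived. Per the labels, parental cells were kept in medium with whole serum and phenol red, and LTED cells in medium with 10% serum treated with dextran-coated charcoal, which removes steroid hormones, and no phenol red. Both were seeded in triplicate in 100 mm dishes and held in charcoal-treated serum for 24 h before RNA was taken with Trizol and a column with DNase treatment. Replicates are therefore dishes of 1 culture, with 1 LTED derivative per parental line. The p-values within a line measure the spread between dishes and not between independent derivations. For each gene that spread was pooled over all 8 groups, so SEs and p-values do not give the precision of 1 line's own dishes.

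The authors deposited 1 table of processed values for 54675 probe sets. The log2 values were used as the authors deposited them, already summarized to 1 value per probe set and array. That they are log2 was judged from their range of 1.39 to 14.8, with no missing value. The log base, the summarization method and the normalization are not given in the sources used here. Array medians were 3.96 to 3.98 in MCF-7, 3.81 to 3.87 in ZR75-1, 5.14 to 5.18 in MDA-361 and 5.72 to 5.76 in HCC-1428, so the lines appear to have been normalized separately. Expression levels of genes are therefore not compared between lines. Correlations between arrays of different lines are given only as a check of labels, and separate normalization can lower them. If the logarithm has another base, the differences keep their order and tests but not their fold size. No detection calls or scanner values were used, so levels at the low end of the scale have an unknown share of background.

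Probe sets were named from the platform annotation, with symbols updated through gene identifiers against a RefSeq gene table of GRCh38.p14, which was used only for names and for the order of neighbouring genes. Of the probe sets, 41091 had 1 symbol (41037 matched by identifier), 1801 had several, 62 were control probe sets and 11721 had none here. Those without a single symbol were left out. Each gene was represented by its probe set with the highest mean over all arrays, which gave 19775 genes, 10523 of them with more than 1 probe set. Counts by direction of a gene's other probe sets were kept, and 0 called named values had another probe set called the other way.

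Groups and replicate numbers came from the labels. No pair of arrays held identical values. Arrays correlated with those of the other state of their own line at 0.983 or more on average and with arrays of other lines at 0.929 or less. Whether equal replicate numbers pair dishes was checked through the correlation of their deviations from the group means. The 12 values ran from -0.176 to 0.136 and 2 exceeded 0.1, so the numbers were taken as names only.

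LTED was compared with parental cells in each line with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 fit of 8 group means over the 24 arrays, with Benjamini-Hochberg adjustment per line. A gene was called changed at an adjusted p under 0.05 and at least 2-fold. A change common to the lines was tested on the 8 group means with the line as a block, so that the 4 lines were the replicates. Genes whose LTED effect differed between lines were tested with the moderated F-test over the 3 differences between lines. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 108 tests of 27 lists in 4 lines, and again with an estimated correlation and with fry. The fry p-value tests whether the genes of a list move one way on balance, and its mixed p-value whether they change in either direction. Neither compares a list with other genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

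The comparisons, the lists and the rule for named genes were fixed before the data were examined. The lists were estrogen-induced, estrogen-repressed, luminal identity, basal and mesenchymal, epithelial junction, receptor tyrosine kinase, growth factor ligand and IGF-binding protein, PI3K pathway component, FOXO target, MAPK output, immediate early, cell cycle and E2F target, MYC and ribosome biogenesis, cholesterol biosynthesis and uptake, fatty acid synthesis, interferon-stimulated, antigen presentation, ATF4 and amino acid stress, unfolded protein response, hypoxia and glycolysis, BCL2 family and apoptosis, ERBB2 neighbourhood, xenobiotic and steroid metabolism, fibroblast and stromal, immune cell, endothelial, and neuroendocrine and neuronal genes. They were written from general knowledge and not taken from these samples, and after the annotation was seen only the symbols of GARS1 and SARS1 were updated. Some genes stand on more than 1 list. The rule named the 8 largest rises and 8 largest falls per line among genes past the threshold with non-overlapping arrays, and 8 each way across the lines. The latter were taken by the number of lines passed and then by mean change when none passed the test across lines. It also named up to 2 rises and 2 falls per list, and 14 genes of estrogen receptor and PI3K signalling, of which the 13 with a named probe set here were used. Genes of the sex chromosomes that mark sex and unnamed open reading frames were left out.

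The fits were tested on simulated data made from the real means and spread with known changes. In each line, all of 200 changed genes among 19775 were called at log2 changes of 1.5, 2 and 3, with 0 false calls. Across the lines, 192 of 200 genes changed by 2 were called, with 0 false calls. There, line effects were permuted over genes, so changed genes had the spread of a typical gene, and 200 changed at once. The share is therefore not the power in the real data. In those, GREB1, with a mean change of -1.93 and an SD of 0.38 between lines, had a limma adjusted p of 0.654. The test of differing effects called 200 of 200 genes changed in MCF-7 alone and 15 unchanged genes. The list of cell cycle and E2F target genes, shifted by 0.5, was called in each line, with 0 other calls among 108 tests. Lists that share a gene with it were not counted in the shifted line. The simulated noise was independent between genes, so false calls through correlation between genes could not show. In the real data the estimated correlation of this list was 0.1185.

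Alternatives were quantile normalization of the 24 arrays, median centring, the mean of a gene's probe sets, exclusion of probe sets ending in _x_at or _s_at, exclusion of genes at or below 4.70 (the median of probe set means, leaving 12689 genes), a trended and robust prior, array weights, the 6 arrays of a line alone, the replicate number as a block, other thresholds, and leaving out each array or line. Leaving out MDA-361 parental replicate 2 everywhere was added after seeing the data. Another pseudocount, listed in case the values were linear, did not apply to log2 values. Splits of the arrays into other groups were counted, with 100 random ones where there were more.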

Results

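Gene expression was measured on 24 Affymetrix arrays of RNA from 4 human breast cancer cell lines, MCF-7, ZR75-1, MDA-361 and HCC-1428. Each line was represented by its parental cells and by a long-term estrogen-deprived (LTED) derivative, that is, cells kept in medium whose serum had been stripped of steroids with charcoal. Each of the 8 groups had 3 arrays. All cells, parental cells included, spent the last 24 h before harvest in medium with 10% stripped serum, so a difference between the groups of a line compares lasting with brief estrogen withdrawal. Array medians on the deposited log2 scale lay between 3.81 and 5.76 and differed more between lines than between parental and LTED cells, so LTED cells were compared only with their own parental line. The number of arrays limits the precision, and changes that start or end near the low end of the scale have an uncertain size. The comparisons ask which transcripts differ once cells have grown without estrogen, and the series title names PI3K signalling in this setting.

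In MCF-7, interferon-stimulated genes and estrogen-induced genes fell in the LTED cells. NPY1R, a neuropeptide Y receptor gene, had the largest fall, from 9.20 ± 0.12 to 2.93 ± 0.12 (log2, SD, n = 3), a change of -6.27 ± 0.08 (SE). The other large falls were those of IFI44L (-4.92), MGP (-4.55), PGR (-4.22), IFI44 (-3.80), TCN1 (-3.72), SAMD9 (-3.68) and IFIT3 (-3.63). TEX19, a gene normally active in germ cells, rose by 3.27 ± 0.08, followed by FBN2 (3.18), LINC01419 (3.04), ERBB4 (2.97), TNFRSF11B (2.50), NDN (2.46), ACTG2 (2.29) and MXRA5 (2.18). Of 40 interferon-stimulated genes, 31 fell past the threshold over all genes and 31 adjusted over the list alone, and the list median was -1.91 (camera adjusted p = 9.5e-67). Antigen presentation genes fell with them (median -0.70, adjusted p = 2.6e-13), with 5 of 20 past the threshold, among them PSMB9 (-2.05) and HLA-B (-1.57). Of 31 estrogen-induced genes, 12 fell past the threshold, 12 adjusted over the list alone, and none rose past it, led by PGR and PKIB (-3.10), with a median of -0.88 (adjusted p = 3.4e-21).

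Several other lists shifted in MCF-7 by smaller amounts. Luminal identity genes fell (median -0.15, adjusted p = 1.0e-04), with MUC1 (-1.58) and TFAP2C (-1.06) past the threshold. Xenobiotic and steroid metabolism genes fell (median -0.13, adjusted p = 8.6e-04) with AKR1C2 (-2.20) and AKR1C1 (-1.72) past the threshold, and hypoxia and glycolysis genes fell (median -0.16, adjusted p = 1.9e-06) with none of 28 past the 2-fold minimum. With the mean of probe sets these medians were -0.06 and -0.10, and without replicate 1 of every group the former was -0.08. Cell cycle and E2F target genes rose (median 0.24, adjusted p = 1.1e-09), with 25 of 44 past the adjusted p and none past 2-fold. The camera adjusted p of this list was 0.0346 with an estimated correlation. MYC and ribosome biogenesis genes rose (median 0.21, adjusted p = 1.8e-06; adjusted p = 0.0668 with an estimated correlation), and fatty acid synthesis genes fell (median -0.09, adjusted p = 0.0176; adjusted p = 0.0668 with an estimated correlation), among them ELOVL5 (-1.12), with a median of -0.06 without replicate 1 of every group. Single genes of other lists also moved, such as DUSP4 (-2.56) and EGR1 (1.81) among MAPK output genes and EGR3 (-1.81) among immediate early genes. FGF12 (1.36), which stands on the list of growth factor ligands and IGF-binding proteins, rose. In all, 268 of 19775 genes changed at least 2-fold with an adjusted p under 0.05, 52 higher and 216 lower, and at the adjusted p alone 1691 were higher and 2141 lower.

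In ZR75-1 LTED cells, ESR1 on its brightest probe set and the secretoglobin genes SCGB1D2 and SCGB2A2 fell. Estrogen-induced genes fell as a list, with 17 of 31 lower and 6 higher at the adjusted p alone. ESR1, the estrogen receptor gene, went from 9.69 ± 0.09 to 4.04 ± 0.39 (log2, SD, n = 3), a change of -5.64 ± 0.12 (SE) on its brightest probe set. The other ESR1 probe sets did not pass the threshold, and in MDA-361, where the brightest one fell by 1.54, they lay between -0.68 and 0.20. SCGB1D2 had the largest fall (-7.43 ± 0.10), followed by IGFBP5 (-6.96), SCGB2A2 (-6.79), GOLM1 (-5.72), TMSB4X (-5.65), LGALS1 (-5.39) and TMTC1 (-4.60). HS6ST2 rose by 4.17 ± 0.16, followed by CXCL17 (3.41), SOX2 (2.83), STC2 (2.67), CENPV (2.60), BHLHE41 (2.58), PIP5K1B (2.58) and TSPAN8 (2.32). Estrogen-induced genes fell (median -0.48, adjusted p = 5.4e-08), with 12 of 31 lower past the threshold, 12 adjusted over the list alone, led by CTSD (-3.46) and PGR (-3.33), and STC2 as the single member that rose past it. Luminal identity genes fell (median -0.47, adjusted p = 3.3e-10), with 12 of 17 past the adjusted p and ESR1 and KRT8 (-1.54) past 2-fold.

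Genes of amino acid synthesis and the ATF4 response rose in ZR75-1 LTED. Of 31 such genes, 12 rose past the threshold, 12 adjusted over the list alone, and none fell past it (median 0.85, adjusted p = 6.4e-23), among them STC2 and ASNS (2.25). MYC and ribosome biogenesis genes rose (median 0.63, adjusted p = 5.8e-16), with 22 of 25 past the adjusted p, and ODC1 (1.17) and MYC itself (1.03) past 2-fold, and the median was 0.42 with the mean of probe sets. Cell cycle and E2F target genes rose (median 0.29, adjusted p = 1.1e-09), with MCM7 (1.05) past 2-fold but at 0.95 without parental replicate 2 and 0.995 without LTED replicate 3. The camera adjusted p of this list was 0.0346 with an estimated correlation. MAPK output genes fell (median -0.20, adjusted p = 0.00828), with EGR1 (-2.84) and MAFF (-2.66) past the threshold, and the median was -0.08 without replicate 3 of every group. FOXO target genes fell (median -0.35, adjusted p = 1.0e-03; adjusted p = 0.203 with an estimated correlation), among them FBXO32 (-3.00) and IRS2 (-2.37), with a median of -0.19 with the mean of probe sets. Estrogen-repressed genes also fell (median -0.24, adjusted p = 0.00488; adjusted p = 0.0516 with an estimated correlation), among them TP53INP1 (-1.78). Interferon-stimulated genes (median -0.11, adjusted p = 0.0262) and antigen presentation genes (median -0.15, adjusted p = 0.0246) passed the test, with ISG15 (-1.40), PARP9 (-2.00) and HLA-DMA (-1.60) past 2-fold, and failed it with an estimated correlation (adjusted p = 0.428 and adjusted p = 0.158). The interferon-stimulated median was -0.05 without replicate 1 of every group.

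Other list members past the threshold in ZR75-1 went either way. CLDN3 (-3.96), a tight junction gene, THRSP (-3.16), BCL2 (-2.89) and IGFBP4 (-1.86) fell. EGFR (1.19), CYP1B1 (1.29), ATF3 (1.35) and PMAIP1 (1.06) rose, and HSD17B4 (-1.13), STS (-1.16), NDRG1 (-1.29), IER3 (-1.41), COL1A1 (-1.25) and SYT1 (-1.02) fell. PMAIP1 was at 0.99 without LTED replicate 2, and SYT1 was at -0.93, -0.98 and -0.98 without parental replicate 1, parental replicate 3 or LTED replicate 3. FGFR2 (-2.96) and FN1 (-1.50) fell on the probe sets used, but without probe sets ending in _x_at or _s_at their values were 0.36 and 0.03. In all, 484 genes changed, 124 higher and 360 lower, while at the adjusted p alone more were higher (3211) than lower (2893). With the mean of a gene's probe sets in place of the brightest, 321 genes changed.

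In MDA-361, interferon-stimulated genes rose in the LTED cells. Rises of IFI27, OAS2 and IFI44L started below the array medians of this line, so their size is uncertain. IFI27 went from 4.0 ± 0.42 to 11.7 ± 0.04 (log2, SD, n = 3), a change of 7.66 ± 0.14 (SE), and OAS2 (5.96), IFI44L (5.87), BST2 (5.66), APOD (5.15), LYZ (4.35), UGT2B28 (4.27) and CCL5 (4.19) followed. IGFBP5 had the largest fall (-6.06 ± 0.14), followed by AFF3 (-5.51), SHISA2 (-4.25), SCGB1D2 (-3.47), OLFML3 (-3.30), DNAJC6 (-3.12), MMP16 (-3.11) and TNC (-3.07). Of 40 interferon-stimulated genes, 33 rose past the threshold, 33 adjusted over the list alone, and the median was 2.23 (adjusted p = 6.7e-49). Antigen presentation genes rose (median 0.80, adjusted p = 4.4e-13), with 18 of 20 past the adjusted p, among them PSMB9 (1.54) and HLA-DRA (1.5). Of 12 immune cell markers, LYZ alone rose past the threshold (list median 0.09, camera adjusted p = 0.436, fry adjusted p = 5.4e-07).

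Cell cycle and E2F target genes rose in MDA-361 LTED (median 0.48, adjusted p = 1.7e-16), with 38 of 44 past the adjusted p and RRM2 (1.03) past 2-fold, but none past it without parental replicate 2, where RRM2 was at 0.98. Cholesterol biosynthesis and uptake genes rose (median 0.25, adjusted p = 0.00344), with 11 of 19 past the adjusted p and a median of 0.16 with the mean of probe sets. Fatty acid synthesis genes rose (median 0.21, adjusted p = 0.0337; adjusted p = 0.104 with an estimated correlation), with a median of 0.13 without replicate 1 of every group. Estrogen-induced genes split. PGR fell by 2.75 and GREB1 by 2.20, TFF1 rose by 1.89, and the list passed the test with a median of -0.06 (adjusted p = 0.0115; adjusted p = 0.172 with an estimated correlation). That median was -0.12 without parental replicate 2 and -0.22 without replicate 2 of every group. Luminal identity genes fell (median -0.11, adjusted p = 0.0206), among them ESR1 (-1.54) and TBX3 (-1.12), with a median of -0.06 without parental replicate 2 and -0.05 without replicate 2 of every group. This call was lost without replicate 2 of every group (adjusted p = 0.0571), without dim genes (0.0755) and with the mean of probe sets (0.132), and the other camera settings gave 0.00857 to 0.0437. Estrogen-repressed genes, with TP53INP1 (-1.27), had a median of -0.21 (adjusted p = 0.0116; adjusted p = 0.0742 with an estimated correlation). FOXO target genes, with FBXO32 (-1.25), had a median of -0.18 (adjusted p = 8.6e-04; adjusted p = 0.203 with an estimated correlation). PI3K pathway components passed by a small margin (median -0.04, adjusted p = 0.0178), with INPP4B (-1.47) and IRS1 (-1.13) past 2-fold. Their median was -0.0028 under quantile normalization and turned to 0.0047 without replicate 3 of every group, and the call was lost without dim genes (adjusted p = 0.0678, with 0.0136 to 0.0498 under the other camera settings).

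Other MDA-361 genes past the threshold were AKR1C3 (2.40) and PPP1R1B (1.81), which rose, and IGFBP4 (-1.62), FN1 (-1.54), BCL2 (-1.52), DDIT4 (-1.16) and FGFR2 (-1.15), which fell. FGFR2 was at 0.26 without probe sets ending in _x_at or _s_at and at -0.99 without parental replicate 3. In all, 419 genes changed, 232 higher and 187 lower, and at the adjusted p alone 3611 were higher and 2818 lower. Parental replicate 2 of this line stood apart. Its mean correlation with its group was 0.989, against 0.996 or more in the 7 other groups, and its ACTB 5' control probe set lay 0.22 below the 3' one, against 0.72 to 1.42 below on the other 23 arrays. Without this array, an alternative chosen after seeing the data, 457 genes changed, 222 higher and 235 lower, and 395 were among the 419. The medians without it were 2.17 for interferon-stimulated genes, 0.81 for antigen presentation genes, 0.41 for cell cycle genes and 0.28 for cholesterol genes, and were -0.12 for estrogen-induced and -0.06 for luminal identity genes, all past the test.

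In HCC-1428, GJA1, a gap junction gene, had the largest fall (-6.71 ± 0.14, SE), followed by EDIL3 (-5.61), DKK1 (-5.20), ARHGAP36 (-4.87), ZNF385B (-4.49), PCDH10 (-4.47), FGF13 (-4.26) and NDP (-4.22). SPINK13 rose by 6.53 ± 0.26, followed by GPC5 (5.10), GRIA2 (3.44), GUCY1A1 (3.21), IER3 (3.07), PSD3 (2.88), AGTR1 (2.83) and CNTN3 (2.62). ESR1 rose by 1.38 and PGR by 1.06. Luminal identity genes rose as a list (median 0.13, adjusted p = 0.00341), with 8 of 17 past the adjusted p and ESR1 past 2-fold. Interferon-stimulated genes fell (median -0.56, adjusted p = 2.1e-11), with 11 of 40 past the threshold, 11 adjusted over the list alone, led by IFIT1 (-2.38) and IFI44 (-2.16). Unfolded protein response genes rose (median 0.18, adjusted p = 8.2e-04), with 12 of 22 past the adjusted p and none past 2-fold.

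Estrogen-induced genes went both ways in HCC-1428. PDZK1 (-1.73) and EGR3 (-1.62) fell, AGR2 (1.58) and PGR rose, and the list median was -0.20 (adjusted p = 0.028; adjusted p = 0.234 with an estimated correlation). Cell cycle and E2F target genes fell (median -0.22, adjusted p = 5.2e-08; adjusted p = 0.0558 with an estimated correlation), with 21 of 44 lower past the adjusted p. Fatty acid synthesis genes (median 0.22, adjusted p = 0.0262; adjusted p = 0.086 with an estimated correlation) and antigen presentation genes (median 0.15, adjusted p = 0.0262; adjusted p = 0.164 with an estimated correlation) rose, although THRSP fell by 1.39. ERBB4 (1.4), FGFR3 (1.20) and DSP (1.08) rose past the threshold, and ADM (-1.36), BTC (-1.13), COL1A1 (-1.02) and INSM1 (-1.81) fell. In all, 337 genes changed, 106 higher and 231 lower, and at the adjusted p alone 2236 were higher and 2513 lower.

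**Figure D1:**
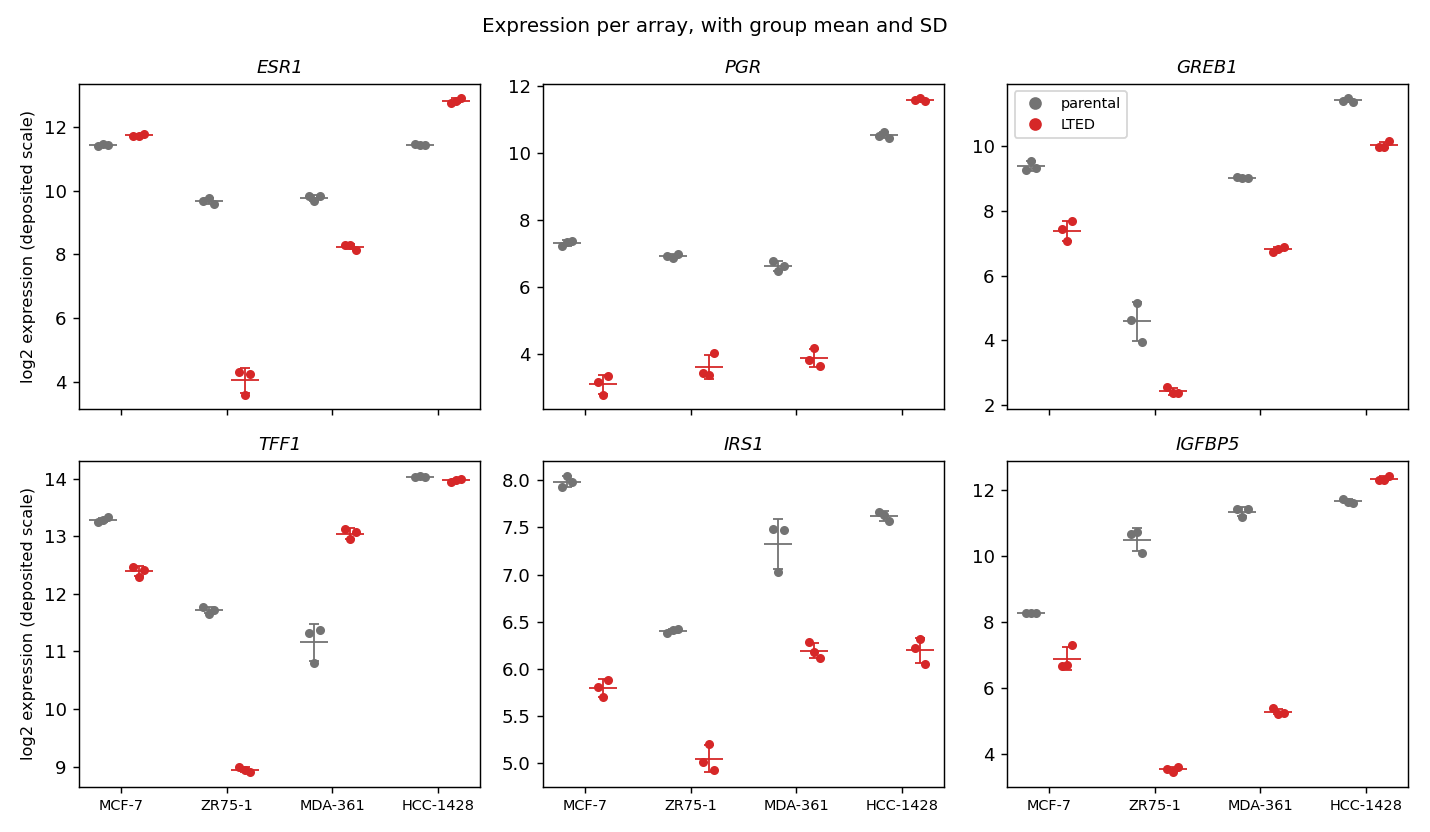
Expression of 6 genes on the deposited log2 scale (vertical axes, which do not start at 0) for the parental (grey) and LTED (red) cells of each line. Points are arrays, and bars show the group mean and SD (n = 3). GREB1 and IRS1 were lower in the LTED cells of all 4 lines, while ESR1 fell by 5.64 in ZR75-1 and rose by 1.38 in HCC-1428.

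Genes of the estrogen receptor and of receptor tyrosine kinase and PI3K signalling were examined in every line. GREB1, an estrogen receptor target, fell in all 4 lines, with -1.99 ± 0.19 in MCF-7, -2.16 ± 0.19 in ZR75-1, -2.20 ± 0.19 in MDA-361 and -1.39 ± 0.19 in HCC-1428 (log2, SE). The SE of a gene is the same in each line because it was pooled over all groups. The SD between GREB1 dishes ran from 0.03 in MDA-361 parental to 0.61 in ZR75-1 parental cells. IRS1, an adaptor of the insulin and IGF1 receptors, also fell in all 4, with -2.18 ± 0.10, -1.35 ± 0.10, -1.13 ± 0.10 and -1.42 ± 0.10 in the same order. PGR fell in MCF-7, ZR75-1 and MDA-361 and rose in HCC-1428. ESR1 in MCF-7 was at 0.31 ± 0.12 (adjusted p = 0.0669), with the pooled SE. The MCF-7 dishes themselves went from 11.43 ± 0.03 to 11.74 ± 0.04 (log2, SD, n = 3) and did not overlap. Changes of the other ESR1 probe sets in MCF-7 lay between -0.05 and 0.66, none past 2-fold. TFF1 fell in ZR75-1 (-2.77) and rose in MDA-361 (1.89). It was at -0.88 in MCF-7 (adjusted p = 4.2e-07) and -0.07 in HCC-1428 (adjusted p = 0.718). IGF1R fell in MCF-7 (-1.74) and MDA-361 (-1.06). It was at 0.41 in ZR75-1 (adjusted p = 7.7e-04) and 0.14 in HCC-1428 (adjusted p = 0.306). IRS2 passed the threshold in ZR75-1 only, although MDA-361 (-0.89) and MCF-7 (-0.65) passed the adjusted p. INPP4B, a phosphatase of the PI3K pathway, rose in MCF-7 (1.07) and fell in ZR75-1 (-1.0) and MDA-361 (-1.47), with -0.86 in HCC-1428 (adjusted p = 3.1e-07). In ZR75-1, INPP4B was short of 2-fold without parental replicate 1 (-0.94), parental replicate 2 (-0.93), LTED replicate 1 (-0.98) or LTED replicate 2 (-0.999). EGFR passed in ZR75-1 alone (1.19). CCND1, INSR, ERBB2 and ERBB3 stayed within 2-fold in each line, from -0.66 for ERBB2 in ZR75-1 to 0.50 for INSR in HCC-1428.

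Several of these calls rested on the choice of the brightest probe set. With the mean of a gene's probe sets, GREB1 stayed lower in every line at an adjusted p under 0.05 but short of 2-fold, with -0.99 in MCF-7, -0.76 in ZR75-1, -0.81 in MDA-361 and -0.58 in HCC-1428. IRS1 was then at -0.94 in ZR75-1 and -0.65 in MDA-361, IGF1R at -0.69 in MDA-361, and INPP4B at 0.84 in MCF-7 and -0.48 in ZR75-1. ESR1 was at -0.78 in ZR75-1 and -0.33 in MDA-361, and EGFR at 0.42 in ZR75-1. The mean also put BCL2, COL1A1, ATF3, HSD17B4, STS, TP53INP1, PMAIP1, SYT1 and PM20D2 in ZR75-1 short of the threshold, and BCL2, FBXO32, TBX3, TNC, TP53INP1, ERBB4 and DOCK11 in MDA-361. It did the same for AKR1C1, ELOVL5 and IGFBP5 in MCF-7 and for BTC, COL1A1, ERBB4, FGFR3, INSM1, DOCK11 and PM20D2 in HCC-1428. Without probe sets ending in _x_at or _s_at, ASNS (0.0289), BHLHE41 (0.09), PIP5K1B (0.31), HEY2 (-0.45), ATF3 (0.28) and PARP9 (-0.38) fell short in ZR75-1. So did MGP (-0.78), AKR1C1 (-0.28) and AKR1C2 (-0.13) in MCF-7, FN1 (-0.14) in MDA-361 and INSM1 (-0.02) in HCC-1428. Quantile normalization put MCM7 (0.98), MYC (0.96), PMAIP1 (0.96) and SYT1 (-0.86) in ZR75-1, RRM2 (0.97) in MDA-361 and BTC (-0.95) in HCC-1428 short of 2-fold. Median centring did so for INPP4B (-0.96) and SYT1 (-0.98) in ZR75-1, and array weights for RRM2 (0.998) in MDA-361.

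Across the 4 lines taken as replicates, limma found 0 genes at an adjusted p under 0.05, the lowest being 0.654. With 4 lines as replicates, this does not show that no change was common. At an unadjusted p under 0.05 there were 1102 genes, where 989 would be met by chance. With the dishes as replicates, which tests the mean of these 4 lines only, 100 genes passed, 14 higher and 86 lower. The genes named here were therefore chosen by the number of lines in which they passed. MPPED2, GREB1 and IRS1 fell in 4 lines, with mean changes of -2.63, -1.93 and -1.52 (limma adjusted p = 0.814, 0.654 and 0.814 across lines). MPPED2 in ZR75-1, at -1.04, was short of 2-fold without parental replicate 1 (-0.97), parental replicate 2 (-0.99) or LTED replicate 3 (-0.93), and at -0.61 with the mean of probe sets. It went from 3.35 to 2.31 there, both below the array medians of that line, so this call rests on dim signal, as does that of INPP4B in ZR75-1 (3.33 to 2.33). IGFBP5, PDZK1 and HEY2 fell in 3 lines, and PGR and S100A8 fell in 3 and rose in the fourth. S100A8 was at -3.57 in MCF-7, -2.72 in ZR75-1, -2.82 in HCC-1428 and 1.62 in MDA-361. ERBB4 and S100P rose in 3 lines, with mean changes of 1.48 and 1.06. CXCL17, GUCY1A1, GUCY1B1, GALNT12, PM20D2 and DOCK11 rose in 2 lines each. GUCY1A1 and GUCY1B1, the subunits of soluble guanylate cyclase, rose together in MCF-7 (1.82 and 1.80) and HCC-1428 (3.21 and 2.14).

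The LTED effect differed between lines for 9762 of 19775 genes (49.4%) by the moderated F-test of limma at an adjusted p under 0.05. Dishes were its replicates, with 1 LTED derivative per line. The test therefore cannot tell a difference between lines from a difference between single derivations. Of 1170 genes changed in at least 1 line, 127 were higher in 1 line and lower in another, and 183 changed in the same direction in 2 or more lines. PGR, S100A8, TFF1, ESR1 and INPP4B were among the named genes that passed in opposite directions. ZR75-1 and MDA-361 shared 46 lower genes, where independent lists would share 3.40, and MCF-7 and HCC-1428 shared 33, against 2.52. Among higher genes, MCF-7 and HCC-1428 shared 10, against 0.279 for independent lists (Fisher's exact test, one-sided adjusted p = 2.9e-13), MDA-361 and HCC-1428 shared 10, against 1.24 (adjusted p = 7.3e-07), and MCF-7 and MDA-361 shared 2, against 0.610 (adjusted p = 0.124). Over all genes, which are not independent replicates, fold changes of pairs of lines had Pearson correlations from -0.08 to 0.15. Genes called in opposite directions also exceeded independent lists in every pair, with 58 against 3.03 for MCF-7 and MDA-361 and 31 against 5.40 for ZR75-1 and MDA-361. The values were 32 against 3.38 for ZR75-1 and HCC-1428 and 16 against 1.77 for MCF-7 and HCC-1428. Fisher's test treats genes as independent and took all 19775, dim ones included, as background, which can make its p-values too small. The shared counts therefore do not by themselves show a common response.

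**Figure D2:**
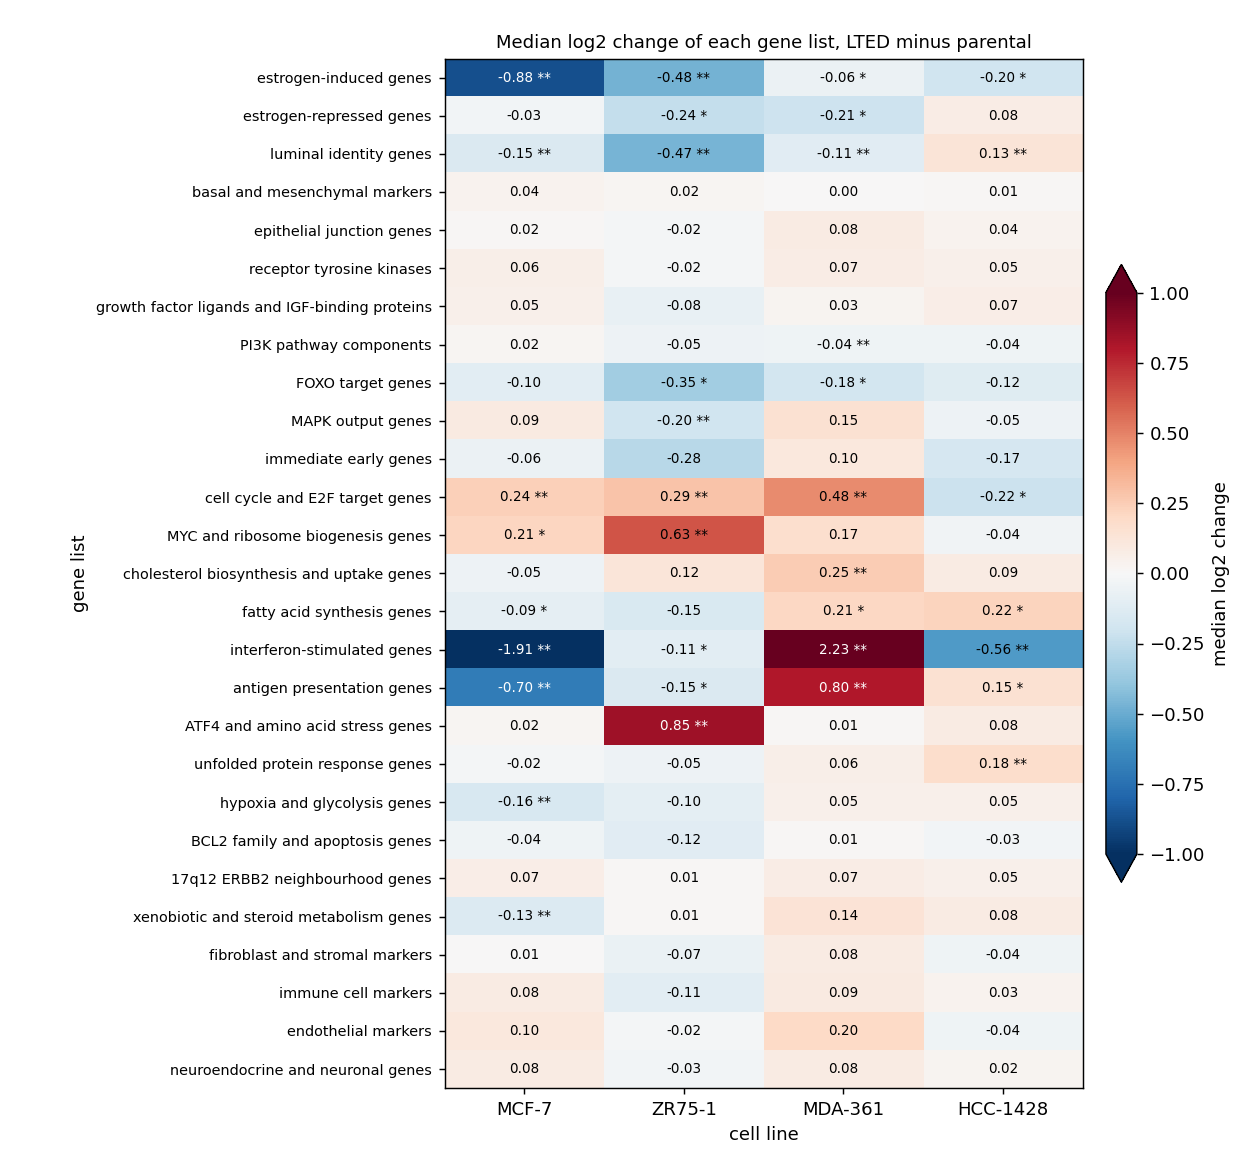
Median log2 change (LTED minus parental) of 27 gene lists (rows) in the 4 lines (columns). Colours are capped at 1 on either side, 1 asterisk marks a camera adjusted p under 0.05 and 2 asterisks mark calls that also held with an estimated correlation between genes. Interferon-stimulated genes span -1.91 in MCF-7 to 2.23 in MDA-361.

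Of 108 tests of 27 lists in 4 lines, 36 passed, 14 upward and 22 downward, and 22 of the 36 held with an estimated correlation. The camera adjusted p of those that held was then larger. It was 1.8e-05 in MCF-7 and 7.0e-05 in MDA-361 for interferon-stimulated genes, and 0.00645 for cell cycle genes in MDA-361. The called lists numbered 9 in MCF-7, 10 in ZR75-1, 10 in MDA-361 and 7 in HCC-1428. Counts of members past the threshold were the same over all genes and adjusted over the list alone in all 108 tests. By camera, 11 lists passed in no line, among them the markers of other cell types. Medians over the lines ran from -0.07 to 0.08 for fibroblast and stromal markers, from -0.11 to 0.09 for immune cell markers, from -0.04 to 0.20 for endothelial markers and from -0.03 to 0.08 for neuroendocrine and neuronal genes. The others were basal and mesenchymal markers (0.004 to 0.04), epithelial junction genes (-0.02 to 0.08), receptor tyrosine kinases (-0.02 to 0.07), growth factor ligands and IGF-binding proteins (-0.08 to 0.07), BCL2 family and apoptosis genes (-0.12 to 0.01), immediate early genes (-0.28 to 0.10) and genes neighbouring ERBB2 (0.01 to 0.07). These medians cover members that moved in both directions. By fry, which does not compare with other genes, 20 of the 44 tests of these lists passed, among them immune cell markers and endothelial markers in MDA-361 (higher, adjusted p = 5.4e-07 and 5.2e-05). In 23 of the 72 tests that did not pass, the median, the mean and the direction of the test differed in sign, and in 0 of the 36 that passed.

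**Figure D3:**
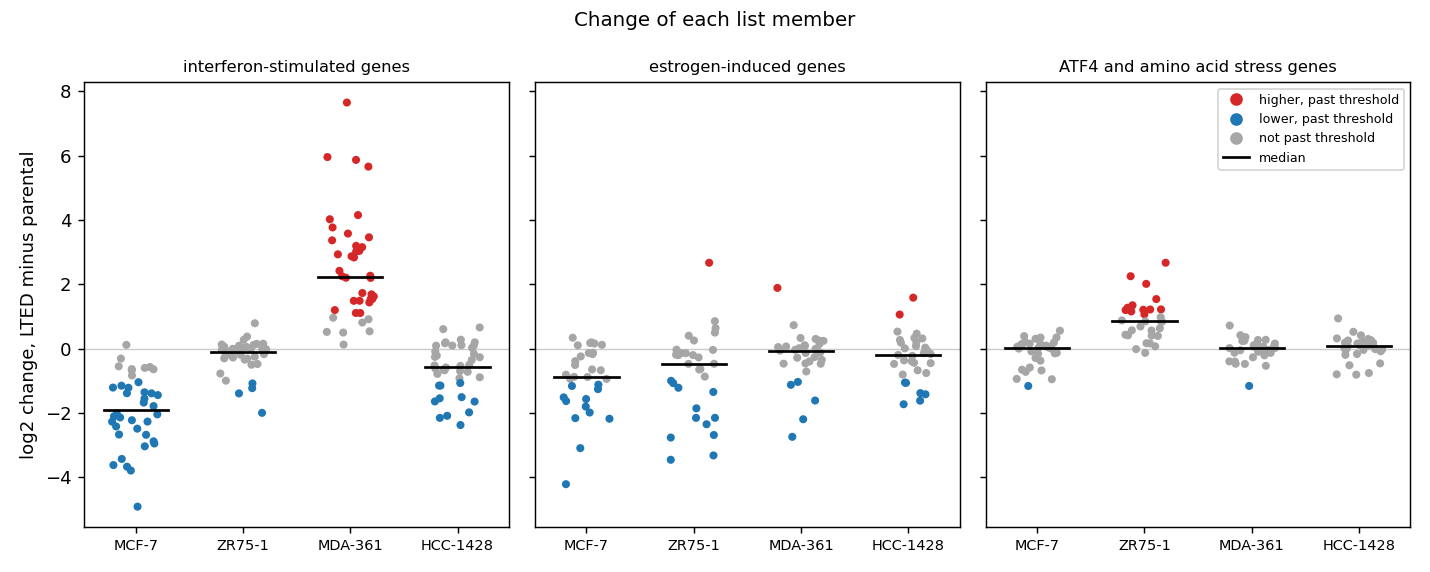
Log2 change (LTED minus parental) of each member of 3 gene lists in the 4 lines. Points are genes, coloured where they passed the threshold, and black bars are list medians. Interferon-stimulated genes lie mostly below 0 in MCF-7 (median -1.91) and above 0 in MDA-361 (median 2.23), and the ATF4 list has a median of 0.85 in ZR75-1.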

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

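The tests of immune cell markers, of the share of interferon-stimulated genes that moved and of the replacement of ZR75-1 by another line were chosen after the results were seen, as was the condition under which the ESR1 probe sets were held too dim to decide.

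The LTED effect differed between the lines by a direct test for each gene and list given here. Dishes were the replicates, with 1 LTED derivative per line, so lines and single derivations cannot be told apart. The widest difference between lines, on the log2 scale, was 7.02 for ESR1, 5.28 for PGR and 4.66 for TFF1. It was 2.54 for INPP4B, 2.17 for IRS2, 2.16 for IGF1R and 1.75 for EGFR. Smaller differences were 1.06 for IRS1, 0.93 for ERBB2, 0.87 for ERBB3, 0.81 for GREB1, 0.77 for INSR and 0.52 for CCND1. Among gene lists, the median over genes of the difference between the most clearly separated lines was 4.31 for interferon-stimulated genes, 1.45 for antigen presentation genes and 0.86 for ATF4 and amino acid stress genes. It was 0.79 for luminal identity genes, 0.74 for cell cycle genes, 0.59 for MYC and ribosome biogenesis genes and 0.50 for estrogen-induced genes. It was 0.32 for fatty acid synthesis, 0.29 for xenobiotic and steroid metabolism, 0.28 for cholesterol, 0.23 for MAPK output, 0.19 for unfolded protein response and 0.19 for hypoxia and glycolysis genes. The differences of 0.35 for estrogen-repressed genes (ZR75-1 against HCC-1428) and 0.35 for FOXO target genes (MCF-7 against ZR75-1) were lost with an estimated correlation, at adjusted p = 0.0697 and adjusted p = 0.345.

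Interferon-stimulated genes moved in opposite directions in MCF-7 and MDA-361. The list median in MDA-361 stayed at 2.17 without parental replicate 2, which argues against that array. Under quantile normalization and median centring the smallest of the medians of both lines was 1.87 in size. Array medians already ran only from 3.96 to 3.98 in MCF-7 and from 5.14 to 5.18 in MDA-361. Rescaling could therefore change little, and it does not decide on the scaling within lines. Of 40 members, 31 fell past the threshold in MCF-7 and 33 rose past it in MDA-361, and 29 did both, an overlap that these counts largely fix, so it is no separate test. Immune cells in the MDA-361 LTED cultures are argued against by their markers, of which 1 of 12, LYZ, rose past the threshold and the other 11 lay between -0.07 (CD2) and 0.27 (NKG7), none past the adjusted p, although fry called the list higher (adjusted p = 5.4e-07). A difference in interferon signalling between the cultures remains as a hypothesis, and whether it came from estrogen deprivation, from an infection or from handling of 1 of the cultures stays open and was not tested.

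ESR1 fell in ZR75-1 LTED. The lowest mean correlation of these arrays with ZR75-1 parental arrays exceeded their highest correlation with any other line by 0.064. Separate normalization of the lines can lower correlations between lines. Within the line, however, these arrays correlated with the parental ones at 0.988 to 0.989 on average, inside the range of 0.983 to 0.992 of the other lines. Changed genes numbered 484, against 268 to 419 in the other lines. These values argue against replacement of the culture by another of the 4 lines. A fault of 1 probe set cannot be told apart from loss of the transcript through the other ESR1 probe sets. Of 3 probe sets above the median of all probe sets, 1 fell at least 2-fold, which by the condition set beforehand pointed to a fault. The others, however, followed the brightest one in HCC-1428 (1.72 and 1.65 against 1.38) but not in MDA-361 (-0.32 and -0.22 against -1.54). By the condition added afterwards they were held too dim to decide. In ZR75-1 parental cells they lay at 4.91 and 5.27, above the median of 4.70 though far below the brightest (9.69). That median was taken over all lines, while the ZR75-1 arrays had medians of 3.81 to 3.87. A further ESR1 probe set, at 4.45 in ZR75-1 parental cells, lay above those and changed by -0.13. The later condition therefore does not set the earlier one aside, and a fault stays open. The fall of estrogen-induced genes such as PGR and CTSD in the same cells is consistent with loss of the receptor, but PGR also fell in MCF-7, where ESR1 did not.

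Other splits of the arrays were counted. The 6 arrays of a line make 10 splits, too few for a share under 0.05. In each line 1 split, the real one, gave as many genes as the real 268, 484, 419 and 337, and the highest other count was 0. For the test across lines, 8 of 8 ways of turning signs gave at least the real count of 0, and they are too few as well. As many list shifts as the real 36 were given by 1 of 100 random splits within lines, the real one included (highest other 25). The other splits mix parental and LTED dishes, which weakens the effect and widens the spread, so the real split was favoured. The dishes are also of 1 culture per group, so this count does not exclude chance differences between cultures. As many shared genes as the real 183 were also given by 1 of 100 (highest other 34), but no other split of a line gave any changed gene, which fixed this outcome, so it does not say whether the lines share more genes than chance would give. For genes with differing effects, 2 of 100 random assignments of arrays to groups gave as many as the real 9762, one of them 11050. Such assignments mix lines, so a count above the real one points to the structure of lines in the samples. With splits within lines only, 1 of 100 gave as many, the real one, and the highest other count was 5150.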

How the results depend on the processing

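Leaving out MDA-361 parental replicate 2 everywhere was the one alternative chosen after seeing the data. Counts of changed genes per line stayed within 1.5 times their value under most alternatives. The exceptions were the mean of probe sets, with 321 genes in ZR75-1, and thresholds with no fold minimum, with 3832 genes in MCF-7, 6104 in ZR75-1, 6429 in MDA-361 and 4749 in HCC-1428. With no fold minimum the overlap of called genes between lines was 4633. The test across lines gave 100 genes with dishes as replicates and 0 under every other setting. The number of list shifts was 22 with an estimated correlation and 76 with fry, which asks another question, and 26 to 39 otherwise. The replicate numbers do not pair the dishes, and with the replicate block the counts were 268, 484, 419 and 337, as without it, with 9621 genes whose LTED effect differs between the lines and 36 as the number of gene list shifts. Over 3989 values of named genes under alternatives, 3871 kept direction and side of the threshold, 84 fell short of it, 23 passed it newly and 11 changed sign. The 84 came from 55 of 228 named values, most of them with the mean of probe sets. The sign changes concerned values near 0 or choices of probe set, and the cause was not tested further. CCND1 in ZR75-1 was 0.0303 with the mean of probe sets. INSR in MDA-361 was -0.0085 with the mean of probe sets and -0.19 with array weights. Without probe sets ending in _x_at or _s_at, FGFR2 was 0.36 in ZR75-1 and 0.26 in MDA-361, and FN1 was 0.0287 in ZR75-1. Leaving out 1 array at a time, CXCL17 in MCF-7 ran from -0.21 to 0.0152, PDZK1 in MDA-361 from -0.0812 to 0.0619 and INSR in MDA-361 from -0.25, without parental replicate 2, to 0.1856. Of 360 values of called lists, 324 kept their call and 36 lost it, most often fatty acid synthesis genes in MDA-361 and HCC-1428 and estrogen-repressed genes in MDA-361. Signal near the floor of the scale makes the size of rises that start there and of falls that end there uncertain, as for IFI27 in MDA-361, HS6ST2 in ZR75-1, FBN2 in MCF-7 and NPY1R in MCF-7.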

Other observations

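The tests of windows of neighbouring genes were not part of the plan, and their thresholds were set before their values were seen. The tests of regional bias and of histone clusters were added once the windows had been seen.

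In some segments, genes that lie next to each other changed together in LTED cells. Over 12660 genes ordered along the chromosomes, medians of the log2 change were taken in windows of 25 genes and set against 1000 shuffled orders. The largest window median was 0.49 in MCF-7, 0.47 in ZR75-1, 0.67 in MDA-361 and 0.57 in HCC-1428, against 95th percentiles of 0.25, 0.33, 0.34 and 0.26 for the shuffled orders (permutation p = 1.0e-03 in each line, the smallest that 1000 shuffles can give). In MCF-7 all 17 such blocks were lower, the longest running over 114 genes from GUSB to PDAP1, of which 98 were lower (median -0.40). Another, from MRS2 to ZSCAN16, had a largest window median of -0.48, and 20 of its 43 genes encode histones. ZR75-1 had 8 higher and 3 lower blocks, among them 53 genes from H3-3A to TARBP1, 44 of them higher. MDA-361 had 7 lower blocks, among them 102 genes from NEURL1 to SPRN (85 lower, median -0.45), and 1 higher block from E2F3 to ZSCAN16, in which 20 of 48 genes encode histones. In HCC-1428 the longest block ran over 212 genes from LINC03124 to USP37, with 182 lower, and 52 genes from CYP11B2 to LRRC14 included 48 higher ones.

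A candidate explanation is that parental and LTED cells differ in the copy number of these segments, which would be a hypothesis from expression alone, since DNA was not analysed here. A regional bias between arrays stays open. Any 1 array set against the other 2 of its group gave a window median of at most 0.29, the value of MDA-361 parental replicate 2, below the smallest LTED value of 0.47, but these are dishes of 1 culture, and a bias shared by the 3 arrays of a group could not show. Of 51 blocks, 46 held no histone gene, so 4 of 4 lines were bound to keep a window beyond the shuffled orders without histone genes. Whether histone gene clusters account for the blocks rich in them, such as those ending at ZSCAN16 in MCF-7 (lower) and MDA-361 (higher), was not tested. Regulation of whole chromosome domains stays open. The blocks held 5.8% of the ordered genes in MCF-7, 3.30% in ZR75-1, 3.02% in MDA-361 and 6.82% in HCC-1428. Of the called genes among the ordered ones, they held 31 of 239 (13.0%), 21 of 425 (4.94%), 20 of 336 (5.95%) and 50 of 250 (20.0%), but blocks were chosen for the size of their changes, which raises these shares by construction.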
